A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

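RNA was measured by sequencing in 9 cultures of the budding yeast Saccharomyces cerevisiae, w303 background, mating type alpha. In every strain the chromosomal PCF11 gene had been replaced by TRP1, and PCF11 was supplied from a plasmid that also carries LEU2. PCF11 encodes a subunit of the machinery that cleaves the 3' end of pre-mRNA and ends transcription. The plasmid held the normal gene (wild type), the pcf11-13 allele (Pcf11-13), or an allele the labels write as pcf11-deltaN-link (Pcf11-DNL), with 3 biological replicates of each. The wild type and Pcf11-DNL genotypes name V5 and MYC tags on the plasmid gene, and the Pcf11-13 genotype names no tag. Cultures grew at 30 °C and were harvested at an optical density (OD600) between 1.0 and 1.2. The growth text also mentions caffeine, but all 9 libraries carry the treatment label glucose. Per the labels, RNA was selected for poly(A) and read as pairs of 150 bases.

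The authors deposited 1 table with a value per gene and library. Their notes name Trimmomatic 0.38, FastQC, STAR 2.6.1b, RSEM 1.3 and DESeq2 1.26.0, with the genome build sacCer3. The part each tool played, its settings, the annotation and the strand setting are not given in the sources used here. The deposited values are expected counts per gene (the estimated read counts that RSEM writes), without normalization. Of all values, 10.8% were not whole numbers, and the library totals lay between 11372819 and 15906466. All 9 columns were used, and replicates were not pooled.

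Of the 5928 genes in the table, 5919 were matched by systematic name to the R64 reference annotation, 5901 as protein-coding genes and 18 as pseudogenes. The other 9 were kept without a position. Positions in the text are those of that annotation.

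Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), which kept 5646 genes and removed 282. Libraries were scaled with TMM, and 1 quasi-likelihood model with a term for the group was fitted to all 9 libraries. Each pair of groups was compared with the quasi-likelihood F test, two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method (threshold 0.05). Every adjusted p for a gene comes from this test. The biological coefficient of variation was 4.59%. Levels are in CPM, the counts of a gene relative to the TMM-scaled total of its library, as mean and SD over the replicates, and changes are log2 fold changes with their standard error. For a gene with no counts in a group, the fold is a lower bound against a floor of 3 counts per library, which covers counting error alone.

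Lists of genes by function, and a list of protein-coding genes that start within 1000 bp downstream of an independently transcribed snoRNA or snRNA gene on the same strand, were written before the data were examined. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation between genes 0.01, two-sided), adjusted over the lists within a comparison. Each was also tested with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The snoRNA list was further compared with 10000 random gene sets matched on mean expression. Overlap and correlation between the mutants were set beside 100 simulations of unchanged groups that share their controls.

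The genes named were chosen by a rule written before the data were examined. It takes PCF11, TRP1 and LEU2. It then takes the 8 highest and 8 lowest log2 fold changes of each mutant against wild type among genes past the threshold, with a mean of at least 5 CPM and no overlap between the libraries of the groups. Between the mutants it takes the 6 highest and 6 lowest. Of each list described it takes up to 4 members with the smallest adjusted p in the main direction. Chance alone would keep the libraries of 3 against 3 from overlapping in 10% of genes. Genes named outside the rule are said to be so.

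Alternatives were DESeq2 size factors, library totals, TMM computed without the ribosome and stress genes, no filter, a filter at a mean of 5 CPM, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, fits of the compared groups alone, replicate number as a block, a minimum fold of 1.5, and leaving out each library. Added after the data were seen were the block within the 6 libraries of Pcf11-13 and wild type, lists without PCF11, and the snoRNA list without ribosome and stress genes. Replicate number was examined as a pairing through the correlation of residuals. Same-number libraries of Pcf11-13 and wild type correlated at 0.395, 0.214 and 0.145, and those of the other pairs of groups did not follow their numbers.

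The pipeline was tested on simulated data with changes added to known genes. It recovered 66% of added changes of 1.2-fold and 94% of those of 1.5-fold in the design of Pcf11-13 against wild type, and 58% and 93.9% in that of Pcf11-DNL against wild type. No snoRNA gene is in the table, so snoRNA levels were not analysed here.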

Results

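The total of expected counts was 13107636, 14021049 and 11372819 in Pcf11-13 replicates 1, 2 and 3. It was 15061381, 14642236 and 13273544 in Pcf11-DNL, and 12361071, 14660581 and 15906466 in wild type. The leading principal component, with 72.4% of the variance, set the Pcf11-13 libraries apart, and the next held 10.1%. Wild type replicate 1 stood apart from its group. Its chi-square per degree of freedom against the other wild type libraries was 10.7 and 10.1, and the other pairs of replicates lay between 2.5 and 4.71. Without it, 1935 genes were higher and 1709 lower in Pcf11-13, and 473 and 201 in Pcf11-DNL. The Pcf11-13, Pcf11-DNL and wild type groups each held 3 replicates, so every mean below has n = 3.

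PCF11 itself (YDR228C, chromosome IV, 921926 to 923806, minus strand, counts over the whole gene; the reference position of the deleted copy) was the gene altered in these strains. Its transcript stood at 84.7 CPM ± 3.05 (SD, n = 3) in wild type, 648 ± 32.3 in Pcf11-13 and 67.4 ± 2.56 in Pcf11-DNL. It was 7.64-fold higher in Pcf11-13 (log2 fold change 2.93 ± 0.05 SE, edgeR adjusted p = 1.56e-16) and 0.795-fold of wild type in Pcf11-DNL (−0.33 ± 0.05, edgeR adjusted p = 0.00072), in all 3 libraries of each mutant. LEU2 (YCL018W, chromosome III, 91324 to 92418), the leucine synthesis gene that marks the plasmid, fell by 0.71 on the log2 scale in Pcf11-13 (edgeR adjusted p = 1.53e-09), from 199 ± 6.92 to 122 ± 3.98 CPM. In Pcf11-DNL LEU2 was higher by 0.14 (edgeR adjusted p = 0.0447). That call was lost with DESeq2 size factors (0.0606), with the DESeq2 Wald test (0.072), in a fit of those groups alone (0.0598) and without any single library of either group (0.0521 to 0.157). TRP1 (YDR007W, chromosome IV, 461842 to 462516), the marker of the PCF11 deletion, had log2 fold changes of −0.07 in Pcf11-13 (edgeR adjusted p = 0.173) and 0.05 in Pcf11-DNL (0.489). In Pcf11-13 it turned to 0.14 under library totals (0.021) and passed the test at −0.12 without Pcf11-13 replicate 3 (0.0395). The LEU2 counts can include reads from the chromosomal leu2 locus, and any reads of a PCF11 segment missing from the Pcf11-DNL plasmid would be absent there.

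**Figure D1:**
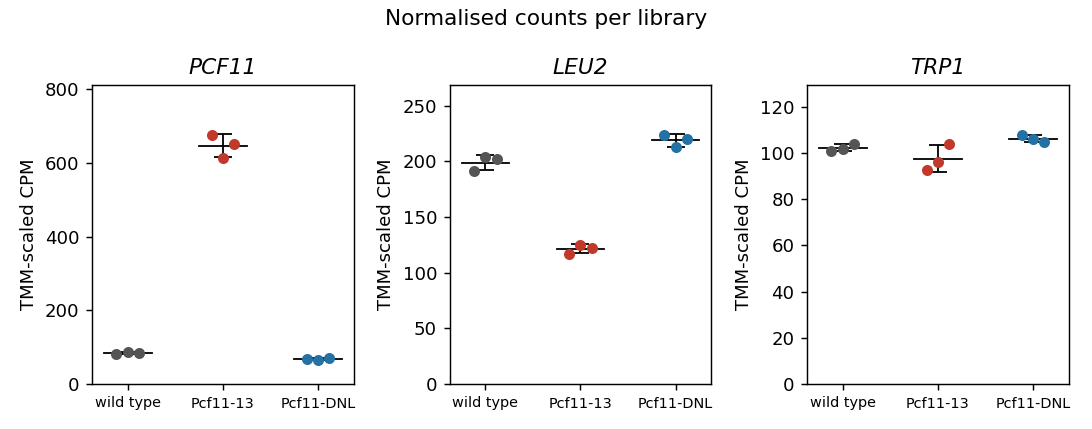
CPM after TMM scaling of PCF11, TRP1 and LEU2 in each of the 9 libraries (points), with the mean of each group and its SD as error bar (n = 3). The Pcf11-13 libraries lie far above the others for PCF11, at a mean of 648 against 84.7 in wild type, and below them for LEU2; the sign of the TRP1 difference in Pcf11-13 turns under library totals.

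The comparison of Pcf11-13 with wild type asks which transcripts differ between strains that carry this allele and the normal gene. Of these groups only the wild type genotype names tags, and PCF11 was 7.64-fold higher in Pcf11-13. Neither difference can be separated from the allele. Among genes with a mean of at least 5 CPM and no overlap between the groups, those with the highest fold changes included CTO1, USE1, YDR042C and HEM4, which lie directly downstream of snoRNA genes. CTO1 (YCR015C, chromosome III, 141217 to 142170) rose 20.3-fold, from 21.8 CPM ± 1.95 (SD, n = 3) to 444 ± 6.51, and starts 193 bp past SNR33. USE1 (YGL098W, chromosome VII, 317342 to 318079), a factor of membrane traffic between Golgi and endoplasmic reticulum, rose 16.3-fold, from 27.8 ± 2.5 to 454 ± 18.4, and starts 286 bp past SNR82. YDR042C (chromosome IV, 540601 to 541203), of unknown function, rose by 3.89 ± 0.06 on the log2 scale and starts 398 bp past SNR47. HEM4 (YOR278W, chromosome XV, 842817 to 843644), an enzyme of heme synthesis, rose 7.12-fold, from 26.7 ± 1.1 to 190 ± 3.83, 210 bp past SNR5.

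Of the 34 genes within 1000 bp downstream of a snoRNA or snRNA gene, 20 rose, 11 fell and 3 did not pass in Pcf11-13, also 20 and 11 adjusted over the list alone. Their median log2 fold change was 0.24 (0.45 under library totals, with 22 higher and 8 lower) and their mean 0.71. The set test gave an adjusted p of 2.3e-16 (adjusted p = 0.0522 with an estimated correlation). None of 10000 random sets matched on mean expression reached the median of 0.24. The middle 95% of them lay between −0.21 and 0.05. In this list 11 of 34 genes rose to a log2 fold change above 1, against 302 of all 5646 genes. Besides the genes above these were FLX1 (2.12), NVJ2 (1.98), UBX6 (1.56), SFT1 (1.24), TRS31 (1.20), SMC5 (1.17) and BUD22 (1.02). They were singled out after their values were seen. All 11 start within 500 bp of the snoRNA gene, where 22 genes had a median of 0.86, and the 12 genes farther away had a median of −0.02. In contrast, the dihydrofolate reductase gene DFR1 fell by 0.90 and the ribosomal protein gene RPS14A fell by 0.89 on the log2 scale. The 75 genes near a snoRNA gene in any other placement had a median of −0.21, with 3 above 1. POL4, a DNA polymerase gene behind CTO1, also rose (2.44), and was singled out after its value was seen. The strand setting of the counting is not known, so these counts cannot be assigned to full-length mRNA of the downstream gene.

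**Figure D2:**
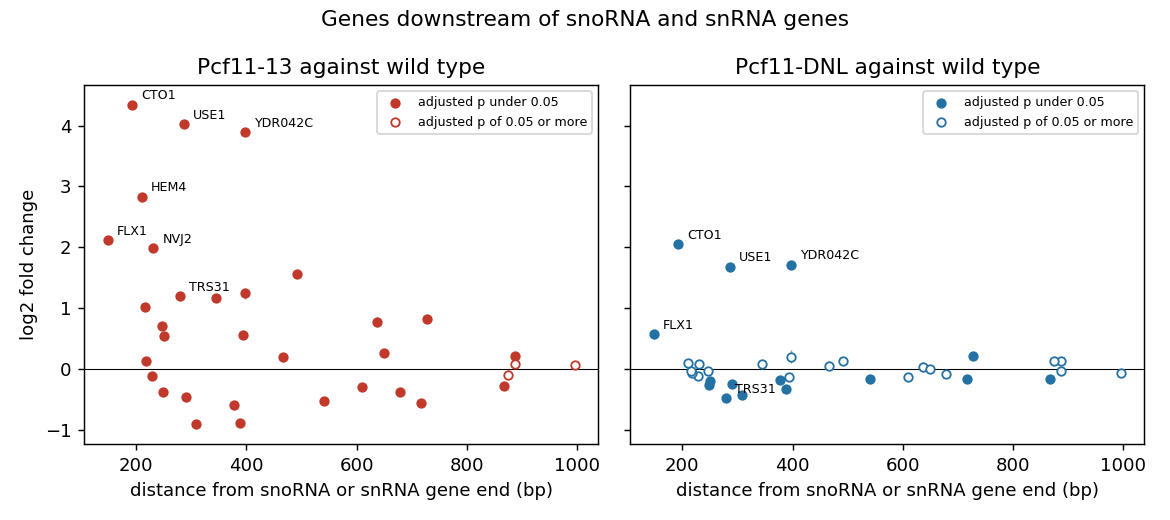
Log2 fold change against wild type of each of the 34 genes that start within 1000 bp downstream of a snoRNA or snRNA gene on the same strand, by distance in bp from its end, in Pcf11-13 and in Pcf11-DNL (filled points passed the gene test; bars, SE). In Pcf11-13 11 genes lie above 1, all within 500 bp, and in Pcf11-DNL 3 genes do; the Pcf11-DNL median turns from −0.03 to 0.02 under library totals.

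Ribosome genes were lower and stress-induced genes higher in Pcf11-13. Of 135 cytosolic ribosomal protein genes 130 fell and 1 rose, with the same numbers adjusted over the list alone. The median was −0.44 (set test adjusted p = 6.2e-30, adjusted p = 0.156 with an estimated correlation). Under library totals 109 of these genes were lower and 2 higher, at a median of −0.23. RPL21B (−1.41), RPS14A, RPS25A (−0.83) and RPS8A (−0.79) had the smallest p-values among them. Their share of all counts was 17.1% ± 0.569 (SD, n = 3) in wild type and 14.3% ± 0.245 in Pcf11-13. Of 128 ribosome biogenesis genes 125 fell and 1 rose (126 and 1 adjusted over the list alone). The median was −0.49 (set test adjusted p = 8.03e-24, adjusted p = 0.31 with an estimated correlation). Library totals gave 107 lower and 2 higher, at a median of −0.28. GCD10 (YNL062C, chromosome XIV, 508776 to 510212), a subunit of a tRNA methyltransferase, fell by 1.76 ± 0.05 on the log2 scale, and the ribosome assembly factor NOC4 fell by 0.79. Of 85 stress-induced genes 75 rose and 2 fell (76 and 2 adjusted over the list alone). The median was 0.85 (set test adjusted p = 5.95e-18, adjusted p = 0.139 with an estimated correlation). HSP12 (2.24), GPH1 (1.69), GDB1 (1.44) and RIM15 (0.95) led it by p-value. The list took 0.443% ± 0.0289 of counts in wild type and 0.787% ± 0.0416 in Pcf11-13. Of 20 trehalose and glycogen genes 16 rose and 2 fell, and likewise adjusted over the list alone. Their median was 0.70 (set test adjusted p = 4.56e-07, adjusted p = 0.165 with an estimated correlation). GPH1 and GDB1 are in this list too, with PGM2 (1.16) and the glycogen synthase gene GSY2 (0.91). Of 43 chaperone genes, which assist protein folding, 16 rose and 16 fell, also adjusted over the list alone, and 26 rose and 10 fell under library totals. Their median was 0.09 (0.30 under library totals) and mean 0.07, and the test direction was down (set test adjusted p = 0.774). Many ribosomal protein genes come as near-identical pairs that share reads, so the values of single members such as RPL21B are uncertain.

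Glucose-repressed genes were mostly higher and phosphate starvation genes mostly lower in Pcf11-13. Of 40 glucose-repressed genes 26 rose and 4 fell (27 and 4 adjusted over the list alone, 33 and 1 under library totals). Their median was 0.59 (set test adjusted p = 1.65e-05, adjusted p = 0.0522 with an estimated correlation). Among them were the regulator gene ADR1 (1.81), the glycerol phosphate dehydrogenase gene GUT2 (1.65) and the hexose transporter genes HXT5 (1.46) and HXT7 (1.06). HXT7 shares reads with a near-identical copy. Of 23 phosphate starvation genes 17 fell and 3 rose, with the same numbers adjusted over the list alone (15 and 6 under library totals). Their median was −0.63 (set test adjusted p = 8.73e-07, adjusted p = 0.31 with an estimated correlation). These included the phosphatase genes PHO12 (YHR215W, −2.06), PHO11 (YAR071W, −1.81), which are near-identical, and PHO5 (−1.54), the regulator gene SPL2 (−1.47) and the small gene PHM6 (YDR281C, −1.95). Without wild type replicate 1, which was high for several of them, 16 fell and 3 rose, at a median of −0.60. The iron regulon did not pass as a list (set test adjusted p = 0.0586, adjusted p = 0.514 with an estimated correlation), but passed under library totals (0.0392) and without wild type replicate 1 (0.0279) or 3 (0.0487). Of its 32 genes 12 fell and 9 rose, also adjusted over the list alone (9 and 16 under library totals), and the median of −0.03 turned to 0.18 under library totals. The multicopper oxidase gene FET3 (YMR058W, chromosome XIII, 388822 to 390732) fell by 1.81 ± 0.06 from 332 CPM ± 26.5, and the reductase gene FRE4 (YNR060W) fell by 1.84 on the log2 scale.

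A list of 23 genes, PCF11 included, was drawn up as candidates for attenuation by early termination. Of them 14 rose and 3 fell in Pcf11-13 (15 and 3 adjusted over the list alone). Their median was 0.24 (set test adjusted p = 1.53e-08, adjusted p = 0.139 with an estimated correlation). GSC2, a subunit of cell wall glucan synthase also called FKS2, rose by 1.47 and the serine synthesis gene SER3 by 1.29. Without PCF11, left out after the data were seen, the median was 0.23 (set test adjusted p = 1.57e-05, adjusted p = 0.268 with an estimated correlation). Of 39 termination and nuclear RNA decay genes 27 fell and 2 rose, also adjusted over the list alone, but 9 fell and 11 rose under library totals. Their median was −0.21, which is 0 under library totals. The set test did not pass (adjusted p = 0.0517, adjusted p = 0.563 with an estimated correlation). It passed with replicate number as a block (0.0487), with DESeq2 size factors (0.0465), with TMM without ribosome and stress genes (0.047), and without Pcf11-13 replicate 1 (0.0383) or wild type replicate 2 (0.0372) or 3 (0.0384). The RNA helicase gene MTR4 fell by 0.73 and the exosome nuclease gene DIS3 by 0.47. Of 26 genes of 3' end processing, PCF11 among them, 6 rose and 8 fell, also adjusted over the list alone (17 and 3 under library totals). The median was −0.04 (0.17 under library totals), the mean 0.13 and the test direction up (set test adjusted p = 0.252). Without PCF11 the median was −0.07 (set test adjusted p = 0.992). Of 11 histone genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, 5 and 2 under library totals). Their median was −0.23 (set test adjusted p = 0.0172, adjusted p = 0.393 with an estimated correlation), and HTB1 fell by 0.57.

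Among the other genes that the same limits ranked highest, NCE103 (YNL036W), a carbonic anhydrase gene, rose 5.56-fold to 254 CPM ± 48.5, ATG39 (YLR312C), an autophagy receptor gene, rose by 2.50, and COS4 (YFL062W), of a repeated subtelomeric family, rose by 2.64. BSC1 (YDL037C) fell by 1.73 on the log2 scale. The Ty element reading frame YGR027W-A had no counts in any Pcf11-13 library and 25.6 CPM ± 1.38 in wild type, at least 102-fold lower. COS4 and the Ty reading frames share reads with near-identical copies and are uncertain.

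In all, 1988 genes were higher and 1744 lower in Pcf11-13 (edgeR quasi-likelihood test, adjusted p under 0.05), of which 292 and 35 changed at least 2-fold. Of 34 lists 17 passed the set test, none of them with an estimated correlation. Under library totals 3372 genes were higher and 861 lower, 79.7% higher against 53.3%, and the median of all genes was 0.245 against 0.032, so the split into higher and lower depends on the scaling. With replicate number as a block in the 6 libraries of these groups, 1996 genes were higher and 1851 lower. No label gives a pairing, and the block rests on the residual correlations of same-number libraries. The lowest of these was 0.145, and Pcf11-13 replicate 2 with wild type replicate 3 reached 0.133.

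The comparison of Pcf11-DNL with wild type asks the same of the second allele. CTO1, YDR042C and USE1 again had the highest changes among genes past the test with a mean of at least 5 CPM and no overlap between the groups. CTO1 rose 4.14-fold to 90.7 CPM ± 3.06 (SD, n = 3), YDR042C 3.28-fold to 38.2 ± 1.65 and USE1 3.2-fold to 89.3 ± 2.52, each in all 3 libraries. HEM4 did not pass (log2 fold change 0.11, edgeR adjusted p = 0.26), and the protein traffic gene TRS31 behind SNR13 fell by 0.48 on the log2 scale. Some genes of iron and phosphate uptake fell, FET3 by 0.87 ± 0.06, to 181 CPM ± 13.9, and FRE4 by 0.79. The siderophore transporter gene SIT1 fell by 0.77 and the phosphate transporter gene PHO89 by 0.74 on the log2 scale.

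Of 32 iron regulon genes 12 fell and 1 rose in Pcf11-DNL (18 and 3 adjusted over the list alone, 9 and 2 under library totals). Their median was −0.16 (set test adjusted p = 1.21e-09, adjusted p = 0.171 with an estimated correlation). The cell wall iron-binding protein genes FIT2 (YOR382W, −1.05) and FIT3 (YOR383C, −0.70) and the permease gene FTR1 (−0.50) were among them. Of 23 phosphate starvation genes 12 fell and none rose (14 and 1 adjusted over the list alone). Their median was −0.22 (set test adjusted p = 2.05e-07, adjusted p = 0.39 with an estimated correlation). PHO12 fell by 0.54 and the transporter gene PHO84 by 0.41 on the log2 scale. Wild type replicate 1 was high for these genes, with PHO12 at 1060 CPM against 812 and 801 in wild type replicates 2 and 3. Without it 11 phosphate genes fell and none rose, at a median of −0.16 (set test adjusted p = 7.4e-08). Of 128 ribosome biogenesis genes 6 fell and none rose (5 and 0 adjusted over the list alone, 5 and 1 under library totals). Their median was −0.09 (set test adjusted p = 1.16e-06, adjusted p = 0.866 with an estimated correlation), and the genes that fell included NOG2 (−0.33) and YTM1 (−0.25). Without wild type replicate 1 the median of the ribosome biogenesis genes was −0.05, with 5 lower and 1 higher (set test adjusted p = 0.00106). Of 135 ribosomal protein genes 10 fell and 2 rose (3 and 2 adjusted over the list alone, 3 and 3 under library totals). The median of −0.04 turns to 0.01 under library totals (set test adjusted p = 0.00498, adjusted p = 0.877 with an estimated correlation). The call for the ribosomal proteins ended without Pcf11-DNL replicate 1 (0.0563) or 3 (0.0648) and without wild type replicate 2 (0.0832) or 3 (0.05). Of 85 stress-induced genes 12 rose and 2 fell (13 and 3 adjusted over the list alone, 15 and 0 under library totals). Their median was 0.10 (set test adjusted p = 0.00656, adjusted p = 0.866 with an estimated correlation). The mitochondrial carrier gene PIC2 (0.86) and the chaperone gene SSE2 (0.59) rose. The call for the stress list ended without Pcf11-DNL replicate 1 (0.0563) or wild type replicate 1 (0.0807). Of 26 genes of the G1 to S step of the cell cycle 6 fell and none rose (8 and 0 adjusted over the list alone, 2 and 0 under library totals). Their median was −0.10 (set test adjusted p = 0.000615, adjusted p = 0.152 with an estimated correlation). The cyclin gene CLB5 fell by 0.25 on the log2 scale, a call that ended without wild type replicate 3 (adjusted p = 0.0505). In the 3' end processing list the subunit gene REF2 rose by 0.96 and PTI1 by 0.43. REF2 was also higher in Pcf11-13, at 165, 166 and 166 CPM against 73.7, 75.2 and 75 in wild type. There 6 genes of the list rose and 8 fell. In Pcf11-DNL 4 of the 26 genes of this list rose and 3 fell, also adjusted over the list alone (median 0.01, set test adjusted p = 0.372).

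Of the 34 genes downstream of snoRNA genes 5 rose and 10 fell in Pcf11-DNL (7 and 11 adjusted over the list alone, 7 and 9 under library totals). The median was −0.03, turning to 0.02 under library totals, the mean 0.12 and the test direction up, and the set test did not pass (adjusted p = 0.0687, adjusted p = 0.525 with an estimated correlation, and 0.104 with replicate number as a block). It passed under library totals (0.0458), for genes within 500 bp (0.000692), and without Pcf11-DNL replicate 2 (0.048) or 3 (0.0396). The 22 genes within 500 bp nonetheless had a median of −0.03, and the 12 farther away one of −0.04. Among 10000 matched random sets the median of the whole list lay at percentile 51.8. A median does not show moves in both directions. Of the 34 genes 10 fell, against 243 of all 5646 genes, and 5 rose, against 493. That difference in shares was not tested. CTO1, USE1 and YDR042C were the 3 members above 1, and the mitochondrial carrier gene FLX1 behind SNR68, singled out after its value was seen, rose by 0.57.

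Further genes named by the rule included GRX8 (YLR364W, 1.19), a glutaredoxin gene, YDL186W (1.27), the subtelomeric YLL067C (1.21), and the glyoxalase gene GLO4 (YOR040W, −0.70). The Ty reading frames YAR010C (1.38) and YPR137C-A (−6.61) and YLL067C share reads with near-identical copies, and the call for YAR010C ended with the DESeq2 Wald test (adjusted p = 0.107).

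In Pcf11-DNL 493 genes were higher and 243 lower (edgeR quasi-likelihood test, adjusted p under 0.05), 19 and 4 of them at least 2-fold. Of 34 lists 7 passed, none with an estimated correlation. Under library totals the numbers were 728 and 124 (85.4% higher against 67.0%), and with the DESeq2 Wald test 389 and 299 (56.5%). The lower genes numbered 155 in a fit of these groups alone, and 143, 134 and 129 without Pcf11-DNL replicate 1, 2 or 3.

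**Figure D3:**
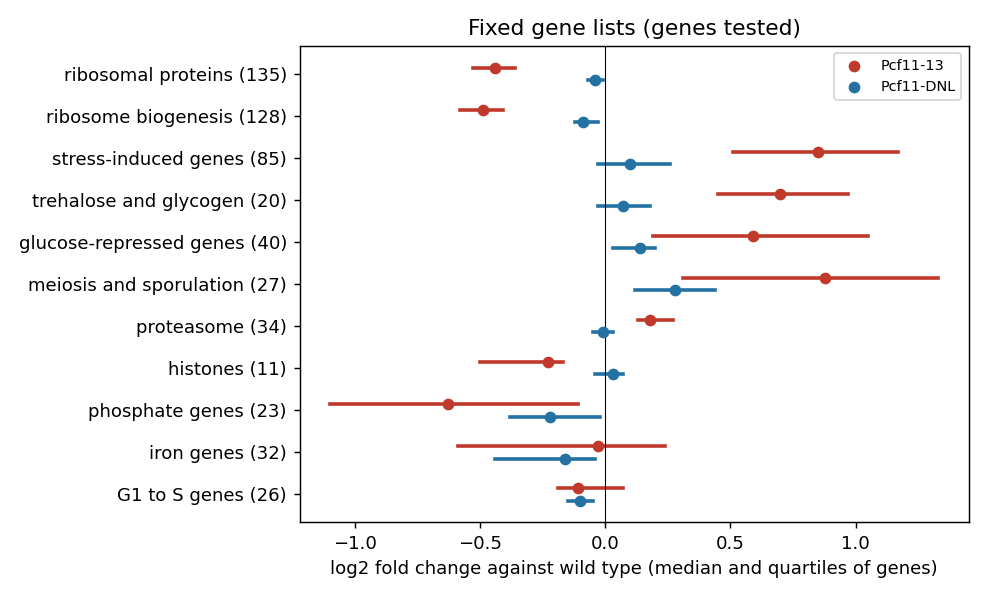
Median log2 fold change (points) with quartiles (bars) of the members of fixed gene lists, in Pcf11-13 and in Pcf11-DNL against wild type. The stress-induced list stands at 0.85 and the ribosomal protein list at −0.44 in Pcf11-13, and at 0.10 and −0.04 in Pcf11-DNL; under library totals the medians of the iron (0.18) and G1 to S (0.10) lists in Pcf11-13 and of the ribosomal protein (0.01) and proteasome (0.04) lists in Pcf11-DNL turn to the other sign.

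The direct comparison of the alleles asks where Pcf11-DNL differs from Pcf11-13. Of these groups only the Pcf11-DNL genotype names tags. That difference and the PCF11 level cannot be separated from the allele. PCF11 was lower in Pcf11-DNL by a log2 difference of −3.27, and HEM4 (−2.73), USE1 (−2.35), CTO1 (−2.29) and the small stress protein gene HSP12 (−2.66) were lower as well, as was the autophagy gene ATG45 (YIL024C, −2.55). HSP30 (YCR021C), which encodes a stress-induced membrane protein, was higher (1.98, from 42.7 CPM ± 1.45 to 168 ± 9.67). GCD10 (1.67) and the chromosome IV neighbours BSC1 (1.80) and PRM7 (YDL039C, 1.78) were higher too. The Ty reading frames YGR027W-A (at least 95.9-fold higher) and YAR010C (2.24) were higher too, with the uncertainty of shared reads.

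Ribosomal protein genes were higher in Pcf11-DNL than in Pcf11-13, 132 of 135 with none lower (133 and 0 adjusted over the list alone). Their median was 0.40 (set test adjusted p = 6.33e-33, adjusted p = 0.136 with an estimated correlation), and RPL21B was higher by 1.32. So were 125 of 128 ribosome biogenesis genes, with 1 lower, also adjusted over the list alone. Their median was 0.43 (set test adjusted p = 1.58e-21, adjusted p = 0.322 with an estimated correlation). Of 85 stress-induced genes 70 were lower and 3 higher, also adjusted over the list alone. Their median was −0.65 (set test adjusted p = 1.02e-18, adjusted p = 0.133 with an estimated correlation). GPH1 (−1.60), GDB1 (−1.47) and PGM2 (−1.42) were among them. Of 34 genes downstream of snoRNA genes 19 were lower and 10 higher (20 and 10 adjusted over the list alone, 23 and 6 under library totals). Their median was −0.25 (set test adjusted p = 1.77e-20), and the call held with an estimated correlation (adjusted p = 0.00639). The glucose-repressed list also held, with 26 of 40 genes lower and 3 higher, likewise adjusted over the list alone. Their median was −0.36 (set test adjusted p = 3.41e-05, adjusted p = 0.0312 with an estimated correlation), with ADR1 at −1.80. These were the 2 of 17 passing lists that held with an estimated correlation.

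Between the alleles 1665 genes were higher and 1742 lower in Pcf11-DNL (edgeR quasi-likelihood test, adjusted p under 0.05), 40 and 166 of them at least 2-fold. Under library totals the numbers were 870 and 2982 (22.6% higher against 48.9%), with a median of all genes of −0.18 against −0.017.

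Genes moved the same way by both alleles included CTO1, USE1 and YDR042C, which rose, and FET3, FRE4, SIT1, PHO12 and PHO89, which fell. In both mutants against wild type 394 genes were higher and 190 lower, and 47 were called in opposite directions. Independent lists of those sizes would share 174 and 75.1 genes and put 238 in opposite directions. Simulated unchanged groups with shared controls gave means of 0.02 and 0.05 genes. Those groups hold no changed gene, so almost none is called. Their overlap therefore cannot show how far shared controls add to the observed one. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.472 and a Spearman correlation of 0.56, against 0.505 and 0.47 in the simulations, and their covariance was 0.0701 against 0.00691, a difference of 0.0632. As no simulated gene changes, the simulated correlations come from noise in the shared controls alone. They are no baseline for data with changed genes, and no conclusion is drawn from setting the correlations beside them. Of the covariance, shared controls alone gave 0.00691 in the simulations. With 3 controls, too few to divide between the comparisons, part of the overlap may come from the shared wild type libraries. Without Pcf11-DNL replicate 1, 2 or 3 the genes lower in both were 115, 112 and 93, and under library totals 652 genes were higher and 71 lower in both.

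**Figure D4:**
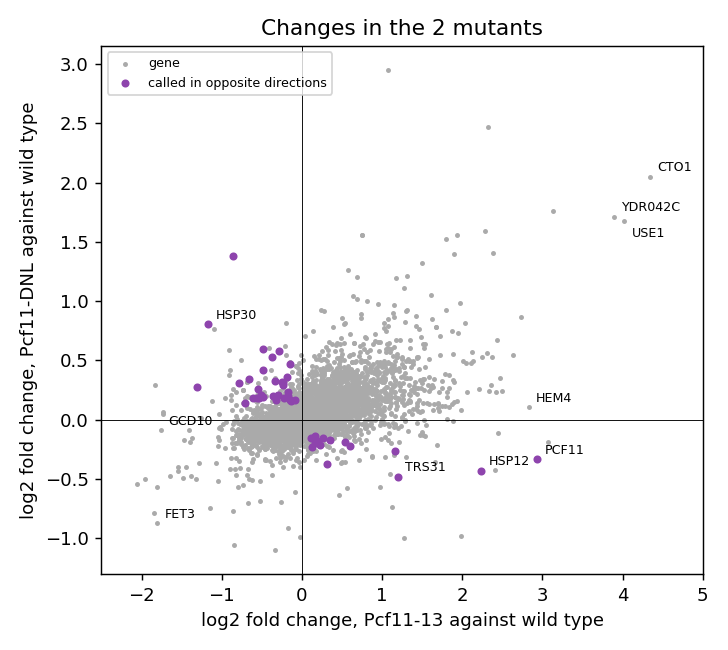
Log2 fold change against wild type of each tested gene (points) in Pcf11-13, horizontal axis, and Pcf11-DNL, vertical axis, with genes called in opposite directions in colour. CTO1, USE1 and YDR042C are high in both mutants, and HSP12, TRS31 and PCF11 lie at the right below 0; 5 genes (YGR027W-A, YGR038C-A, DID2, YLR157C-B and YPR137C-A) lie outside the axes.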

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

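The tests of LEU2 as a measure of plasmid copies and of the attenuation list without PCF11 were chosen only after the result was seen. In all, 47 genes were called in opposite directions in the mutants against the same wild type libraries, so that a difference between the mutants follows from that choice and is given as a value. PCF11 differed most among them, by a log2 difference of −3.27. The stress gene HSP12, at 2.24 in Pcf11-13 and −0.43 in Pcf11-DNL, differed by −2.66. The Ty reading frame YAR010C, which shares reads with near-identical copies, differed by 2.24. HSP30, at −1.17 and 0.81, differed by 1.98. LEU2, at −0.71 and 0.14, differed by 0.85; its call in Pcf11-DNL against wild type was lost with DESeq2 size factors (adjusted p = 0.0606).

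The PCF11 transcript was higher in Pcf11-13 by 2.93 on the log2 scale; more copies of the LEU2 plasmid would raise LEU2 as well, yet LEU2 was at −0.71, below 1.47, the rise taken as the least that copies would give. This argues against copy number as the whole cause, although LEU2 has regulation of its own, and the labels call the plasmid low copy while the vector name they give leaves its copy number in doubt. Transcription running into PCF11 from the neighbouring gene stays open. IVY1, at 0.10, lies 978 bp from the deleted chromosomal locus and on the opposite strand, so its value cannot test this. What flanks the plasmid copy was not measured. Lost early termination inside PCF11 may account for it and stays open as well, because the other genes of the attenuation list had a median of 0.23 but an adjusted p of 0.268 with an estimated correlation. A difference in the plasmid, for example the tags named for wild type and Pcf11-DNL alone, was not tested and cannot be separated from the allele.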

How the results depend on the processing

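The block within 6 libraries, the lists without PCF11 and the snoRNA list without ribosome and stress genes were chosen only after the data were seen. Causes were not tested unless stated. Under library totals, with no factor for composition, 3372 genes were higher and 861 lower in Pcf11-13, 124 lower in Pcf11-DNL, 870 higher and 2982 lower between the alleles, and 652 higher and 71 lower in both mutants; TRP1 turned to 0.14 in Pcf11-13, and between the alleles MF(ALPHA)1, RAD5 and TRP1 turned to −0.007, −0.022 and −0.035. A minimum fold of 1.5, stricter by construction, left 391 and 98, 10 and 2, and 69 and 229 genes higher and lower in the comparisons in turn. Fits of the groups alone, with fewer libraries, gave 155 genes lower in Pcf11-DNL.

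With an estimated correlation 0, 0 and 2 lists passed. The adjusted p-values of the ribosomal protein, ribosome biogenesis and stress lists were then 0.156, 0.31 and 0.139 in Pcf11-13, 0.877, 0.866 and 0.866 in Pcf11-DNL, and 0.136, 0.322 and 0.133 between the alleles, and that of the snoRNA list was 0.0522 in Pcf11-13. With fry 28 lists passed in Pcf11-13 and 27 between the alleles, and in Pcf11-DNL those 3 lists had adjusted p-values of 0.344, 0.344 and 0.146. Ribosomal protein genes without paralog pairs (fewer genes) gave 0.171 in Pcf11-DNL. The snoRNA list in Pcf11-DNL, at 0.0687, passed under library totals (0.0458), with fry (0.0111), within 500 bp (0.000692) and without ribosome and stress genes (0.00131), and stood at 0.104 with replicate number as a block.

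Leaving out each library in turn, genes lower in Pcf11-DNL ranged from 129 to 233, genes lower in both from 93 to 190 and the correlation of the mutants from 0.419 to 0.569. In Pcf11-DNL the adjusted p ranged from 1.03e-06 to 0.0832 for ribosomal protein genes, 0.000378 to 0.0807 for stress genes and 0.0396 to 0.177 for the snoRNA list. Across these libraries PCF11 stayed between 2.90 and 2.97 in Pcf11-13 and between −0.36 and −0.30 in Pcf11-DNL. Among comparisons of a named gene under an alternative, 5108 kept their side of the threshold, 163 lost the call, 1 gained it and 4 reversed. A gene counted as reversed where its sign turned and it passed in either setting. For lists 1003 kept their side, 36 lost the call, 50 gained it and 0 reversed. A list counted as reversed only where both settings passed with opposite test directions, so medians that turned sign are not in that count. Each alternative written before the data were seen was run. At this depth simulated changes of 1.2-fold were recovered in 66%, 58% and 52% of 50 genes in the comparisons in turn, so smaller changes can be missed. Far fewer genes changed in the simulations than were called in Pcf11-13 or between the alleles. The adjusted threshold is stricter then, so these shares may not hold there, and they do not rank the comparisons.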

Other observations

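The tests of distance from the snoRNA end, of the scaling behind the ribosome and stress lists, and of chaperones outside the stress list were chosen only after the result was seen. Further gene groups moved in Pcf11-13. Of 27 meiosis and sporulation genes 19 rose and 2 fell, also adjusted over the list alone, at a median of 0.88 (set test adjusted p = 0.000474, adjusted p = 0.084 with an estimated correlation), with SGA1 at 1.63 and SPS1 at 1.48. In Pcf11-DNL 7 of them rose and 1 fell (9 and 1 adjusted over the list alone, 10 and 0 under library totals; median 0.28, set test adjusted p = 0.000615, adjusted p = 0.152 with an estimated correlation), REC104 by 0.98. All 4 measured alpha mating type genes fell in Pcf11-13, also adjusted over the list alone, MF(ALPHA)2 by 1.04 and SAG1 by 0.80 on the log2 scale. The 4 tested a mating type genes rose, also adjusted over the list alone, ASG7 by 1.52 and STE6 by 0.68. In Pcf11-DNL 3 alpha genes fell (4 adjusted over the list alone), SAG1 by 0.57, and no a gene passed. Lists of fewer than 5 tested genes had no set test.

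Of 34 proteasome genes 26 rose and 1 fell in Pcf11-13, also adjusted over the list alone, at a median of 0.18 (set test adjusted p = 0.0229, adjusted p = 0.64 with an estimated correlation), led by the regulator gene RPN4 (0.79). Of 22 purine synthesis genes 11 rose and 4 fell (13 and 4 adjusted over the list alone, 18 and 3 under library totals; set test adjusted p = 0.02, adjusted p = 0.393 with an estimated correlation), ADE17 by 1.75 and the glycine cleavage gene GCV1 by 1.40. Of 25 genes of the unfolded protein response 13 rose and 2 fell (12 and 2 adjusted over the list alone, 23 and 0 under library totals). The set test gave an adjusted p of 0.00615 (adjusted p = 0.139 with an estimated correlation), and the inositol synthesis gene INO1 rose by 2.05. Of 48 cell wall genes 25 rose and 13 fell, also adjusted over the list alone (36 and 4 under library totals; set test adjusted p = 0.0123, adjusted p = 0.393 with an estimated correlation), PIR3 by 2.06. Of 73 Ty reading frames, which share reads, 44 rose and 9 fell (45 and 9 adjusted over the list alone; set test adjusted p = 0.00104, adjusted p = 0.363 with an estimated correlation). Methionine and sulfur genes, 19 higher and 7 lower of 29, also adjusted over the list alone, did not pass as a list (set test adjusted p = 0.0956), though STR3 (2.37) and MET3 (1.39) rose. The peroxide defence gene SRX1 (2.42), the DNA repair gene MAG1 (1.42) and the endonuclease gene HO (−1.40) changed in lists that did not pass, with set test adjusted p-values of 0.589, 0.0674 and 0.0837.

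The rise of genes downstream of snoRNA genes in Pcf11-13 had a median of 0.24. Closeness to a snoRNA gene in any orientation is argued against by a median of −0.21 in other placements (permutation p = 0.00315, two-sided), and low expression or short length of these genes by 0 of 10000 matched sets reaching the median. Overlap with other genes on either strand concerns 1 of the 34 genes and so cannot carry the rise; the 33 others gave a set test adjusted p of 4.04e-17 (the whole list has an adjusted p = 0.0522 with an estimated correlation). Transcription running on past the snoRNA end may account for the rise and stays open: genes within 500 bp had a median higher by 0.88, at a permutation p of 0.0519. A new start site or a more stable transcript was not tested.

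For the fall of ribosome genes and rise of stress genes in Pcf11-13, the list median nearest 0 over 4 scalings was −0.23 and none changed sign. A scaling shifts all genes of a library alike, so it cannot create the gap between these lists. TMM, DESeq2 size factors and TMM without the ribosome and stress genes gave nearly the same ribosomal protein medians (−0.44, −0.46 and −0.46). All 4 scalings are relative to the other genes of a library. Whether each list changed in absolute amount therefore stays open. With the ribosomal protein genes removed the stress list median was 0.83, against 0.85 with them. TMM scaling already limits the weight of a few abundant genes, so this test could hardly have come out otherwise. It cannot decide whether such genes taking up counts play a part, and it covers the stress list alone. A general response of chaperone genes to unfolded protein stays open: the 37 chaperone genes outside the stress list had a median of 0.02, with 10 higher and 16 lower (set test adjusted p = 0.324). Those counts rest on TMM, since under library totals the whole chaperone list had 26 genes higher and 10 lower. Slower growth of the mutant may also be behind the pattern, and was not tested because growth rates were not analysed here.

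If transcription ran on past mRNA ends, genes behind an abundant gene on the same strand could be higher than genes behind a low one. With 336 and 335 genes, the difference in medians was 0 in Pcf11-13 (permutation p = 0.858, two-sided, 0.858 adjusted over both tests), which leaves transcription running on past mRNA ends in Pcf11-13 open. It was 0.03 in Pcf11-DNL (permutation p = 0.0191, two-sided, 0.0382 adjusted), from medians of 0.02 and −0.01. The permutation shuffles genes, which are not independent replicates, so its p does not cover the spread between cultures. The difference was not recomputed without wild type replicate 1, and no conclusion is drawn from it. Early stops that grow with gene length would lower long genes. In Pcf11-13 the Spearman correlation of change and span across 5293 genes, which are not independent replicates, was −0.0868. Leaving out each library in turn, it ranged from −0.031 (without wild type replicate 1) to −0.117 (without wild type replicate 3). Early stops thus stay open. In Pcf11-DNL the same correlation was −0.237, and −0.0899 without wild type replicate 1.

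Of the 10 ways to split 6 libraries into 3 and 3, only 1, the real one, reached the real number of genes in each comparison. In fits of those 6 libraries the real splits called 3630, 585 and 3553 genes and the highest other split 0. That held too among the 3 others that part the same-number libraries of Pcf11-13 and wild type. Every other split puts libraries of both groups on each side, so the group difference widens the spread and low counts follow. The 0 is thus no support for the calls, and with 10 splits the share cannot fall under 0.05.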
